A study of Homo sapiens with 9 samples.

How the data were processed

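RNA was sequenced from SH-SY5Y cells, a human neuroblastoma line, kept in medium with 5 mM galactose. Per the labels, 3 libraries came from control cells, 3 from cells given 0.35 mM glucosamine each day and 3 from cells given 10 µM Thiamet-G each day, for at least 3 weeks. Glucosamine feeds the hexosamine pathway, which makes the sugar donor for O-GlcNAc, a single-sugar modification of intracellular proteins. Thiamet-G inhibits O-GlcNAcase, the enzyme that removes O-GlcNAc. Libraries were made from 800 ng of total RNA. The series description names a stranded mRNA kit, and the sample records name another TruSeq RNA kit; neither says whether strand was used in counting. The labels do not say whether libraries of a group came from separate cultures.

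Per the series description, the authors checked reads with FastQC 0.11.2 and used RSEM 1.2.22 to align them to hg38 and estimate expression; the submitters' processing notes also name Bowtie2, without a version. The deposited tables hold 1 file per library with 44567 gene symbols. The deposited expected counts are RSEM estimates per gene, not normalized between libraries, and 6.17% to 7.93% of values were not whole numbers. The deposited TPM values are scaled to the transcripts within a library and to transcript length, and the deposited FPKM values to effective length and to aligned reads. The deposited length and effective length columns give bases (other values per gene, not expression). Expected counts were rounded to whole numbers and used throughout, the TPM column entered 1 alternative, and FPKM was not used because it adds nothing to counts for a test between groups. The total per library was 12823935 to 19666213 counts.

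Differential expression followed the test that the series description states for edgeR 3.14.0, run here with edgeR 4.0.16 in R 4.3.3. TMM normalization, a common and then a tagwise dispersion over all 9 libraries (6 residual degrees of freedom) and the 2-sided exact test with a prior count of 0.125 were applied to the 13587 genes kept by filterByExpr. The common biological coefficient of variation was 28.7%. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. CPM values are counts-per-million of the TMM-scaled library, given as mean ± SD (n = 3). The standard error (SE) beside a log2 fold change comes from the spread of log2 CPM (prior count of 2) within the pair of groups. No p-value covers more than the spread between these libraries, which may be technical in part or in whole, since the labels do not give the origin of the replicates. Those of the chromosome permutations cover only the spread between genes.

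Gene groups were 32 lists with 870 entries, drawn from general knowledge. The 29 lists with at least 5 tested members were tested with camera (limma 3.58.1, voom log2 CPM, preset correlation between genes of 0.01), and Benjamini-Hochberg adjustment covered the lists. Camera asks whether the members of a list rank higher or lower than other genes. Counts of changed members were also taken with the p-values adjusted over the list alone. Gene lists, tests, the rule for named genes and the first set of other settings were fixed before the data were examined. The rule named OGT, OGA, GFPT1 and GFPT2 always. Per comparison it named the 8 largest rises and 8 largest falls among genes with a mean of at least 5 CPM and no overlap between the groups, and up to 4 changed members of each list, or up to 2 members as values where none changed. It also named up to 5 rises and 5 falls shared by both treatments.

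Because both treatments were compared with the same 3 controls, 20 data sets with no changed gene were simulated. They gave the values that shared controls produce alone when libraries and genes vary independently. Libraries were described by Euclidean distance and principal components of log2 CPM. Genome positions are hg38 positions from GENCODE 44. Of the 44567 symbols, 26142 matched a GENCODE symbol, 1444 matched through an older symbol and 16981 did not match. GC content was available for 12259 tested genes (90.2%), which is the set used in every GC correction. The correction removed each library's trend of log2 CPM on GC content, fitted as a spline with 5 degrees of freedom, from the counts.

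The other settings fixed at that time were the edgeR quasi-likelihood test, the DESeq2 1.42.0 Wald test, limma-voom, other scalings (RLE, library size only, upper quartile), no filter, a filter of 1 CPM in 3 libraries, log2(TPM + 1) with limma, dispersions from the 6 compared libraries, a replicate block, a log2 fold change of at least 1, an adjusted p under 0.01, camera with an estimated correlation, fry, the 500 most variable genes for distances, and leaving out each library in turn. Added after the data were seen were the GC correction with either edgeR test or with camera, and the omission of control 3 together with glucosamine 1. Where a group was left with fewer libraries, the pooled dispersion was used.

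The tests were run on simulated data with 13587 genes, the depths of the 9 libraries and their dispersions. With 200 changed genes per treatment, the exact test called 89.4% of 4-fold changes for Thiamet-G against control, 83.3% for glucosamine against control and 87.1% between the treatments. It called 25.4%, 28.4% and 27.6% of 2-fold changes, and 2.99%, 4.48% and 4.48% of 1.5-fold changes. Of its calls, 19.6%, 13.5% and 9.71% were unchanged genes, above the share of 0.05 aimed for. The quasi-likelihood test made 4.84%, 5.63% and 7.33% false calls and found 75.8%, 81.8% and 81.8% of 4-fold changes. A GC trend simulated in the glucosamine libraries, on the 12259 genes with a GC value, gave 3045 false calls without correction and 1 with it. The same smooth trend was put into all glucosamine libraries, steeper than the mean difference between glucosamine and control libraries in the data. The 3045 calls therefore do not measure the GC effect in these data. In a simulation without a trend the correction left 86% of 4-fold changes called, against 85% without it. A simulated shift of a list for Thiamet-G against control had adjusted p = 1.3e-09 with the preset and adjusted p = 0.0128 with an estimated correlation, and no other list was called. Genes were drawn independently there, so camera was not tested on lists with correlated members. In the data the estimated correlation was 0.434 for cytosolic ribosomal proteins and 0.932 for mitochondrial DNA-encoded mRNAs (Thiamet-G against control). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.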

Results

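The transcriptome of SH-SY5Y cells was measured by RNA sequencing after long exposure to 1 of 2 treatments that act on O-GlcNAc, the single-sugar modification of intracellular proteins. SH-SY5Y is a human neuroblastoma line. Cells grew in medium with 5 mM galactose, a sugar on which cultured cells rely more on respiration than they do on glucose. Control cells, cells given glucosamine (0.35 mM) and cells given the O-GlcNAcase inhibitor Thiamet-G (10 µM) were each sequenced as 3 libraries. Summed expected counts were 18699812, 19666213 and 12823935 in controls 1, 2 and 3. They were 14942790, 18211658 and 14930417 in glucosamine 1, 2 and 3, and 16296600, 18854832 and 15848364 in Thiamet-G 1, 2 and 3.

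Libraries of either treatment lay closer to each other than to other groups on average, while control libraries lay as far from each other as from the Thiamet-G libraries. The Euclidean distance on log2 CPM was 100.1 ± 16.0 within controls, 86.5 ± 14.9 within glucosamine and 79.9 ± 5.20 within Thiamet-G (SD, 3 pairs each). It was 107 ± 12.7 between control and glucosamine, 99.8 ± 13.2 between control and Thiamet-G, and 95.5 ± 11.8 between the treatments (SD, 9 pairs each), and the mean between groups was 1.13 times the mean within them. The first principal components held 26.7%, 21.2% and 15.3% of the variance. Some libraries stood apart. The mRNAs of mitochondrial DNA made up 18.5% of counts in control 3 and between 3.53% and 8.13% in the other libraries. Small and ribosomal RNA made up 0.601% in glucosamine 1 and between 0.0209% and 0.0733% elsewhere. Expression also followed gene GC content to a different degree in each library: the correlation across genes (which are not independent replicates) of relative expression with GC content was between 0.220 and 0.594 in controls, between -0.644 and 0.0654 with glucosamine, and between -0.335 and 0.603 with Thiamet-G.

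**Figure D1:**
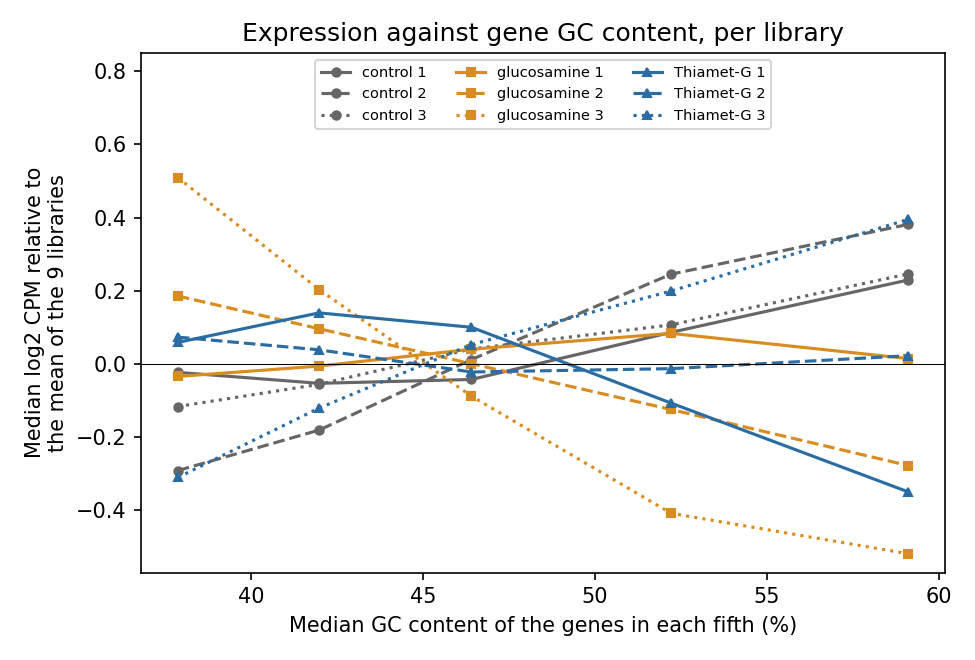
Median log2 CPM relative to the mean of the 9 libraries (vertical axis) in 5 equal sets of genes ordered by GC content (horizontal axis, median GC content in percent), with 1 line per library. For genes of the highest GC content the medians lay at 0.230, 0.382 and 0.246 in the controls and at 0.0145, -0.278 and -0.519 with glucosamine, while the Thiamet-G libraries spanned -0.350 to 0.395.

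Thiamet-G against control asked how expression differs after long inhibition of O-GlcNAcase. MGEA5, the gene of O-GlcNAcase (now named OGA; chromosome 10, 101784443 to 101818465, minus strand), rose by 1.75 on the log2 scale (SE 0.0621, adjusted p = 8.0e-15), from 89.7 ± 4.72 CPM in controls to 303 ± 15.8 CPM. OGT, the gene of the transferase that adds O-GlcNAc (chromosome X, 71533087 to 71575892, plus strand), had 225 ± 2.52 CPM in controls and 205 ± 56.6 CPM with Thiamet-G (log2 fold change -0.14, adjusted p = 0.919). TFPI2, a secreted protease inhibitor (chromosome 7, 93885396 to 93890753, minus strand), rose by 4.03 (SE 0.210, adjusted p = 5.3e-41), from 25.7 ± 4.32 to 422 ± 71.7 CPM; its exons overlap those of GNGT1 on the other strand. The urea-cycle enzyme gene CPS1 (chromosome 2, 210477682 to 210679107) fell from 10.2 ± 1.91 to 2.41 ± 0.644 CPM (log2 fold change -2.08, SE 0.267, adjusted p = 2.2e-06), and was not called with log2(TPM + 1) and limma (adjusted p = 0.278).

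The synaptic vesicle gene SV2C rose from 2.26 ± 0.511 to 18.7 ± 1.998 CPM. RIMS1, a protein of the presynaptic release site, rose by 2.59, PLCXD3 by 2.76, the phosphodiesterase gene PDE7B by 2.89 and RERG by 2.60. GREM1, a secreted BMP antagonist, rose from 6.42 ± 2.10 to 38.7 ± 10.7 CPM. Among the falls, AASS, which starts lysine breakdown, dropped from 9.09 ± 0.267 to 2.02 ± 0.373 CPM and the secreted FGL1 from 40.6 ± 13.2 to 11.6 ± 1.06 CPM. CBLN1 changed by -1.75, and the collagen-modifying PLOD2 by -1.70, a call that was lost without Thiamet-G 2 (adjusted p = 0.058). DBH and HMGA1 changed by -1.92 and -1.91 with wide control values (80.01 ± 52.6 and 37.9 ± 39.4 CPM). Without control 3 neither was called (adjusted p = 0.0562 for DBH and 0.715 for HMGA1), nor was either without Thiamet-G 1 (0.0564 and 0.341), and HMGA1 was also lost without Thiamet-G 2 (0.169) or Thiamet-G 3 (0.0594). With log2(TPM + 1) and limma FGL1, CBLN1 and PDE7B were not called (0.0602 to 0.102).

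**Figure D2:**
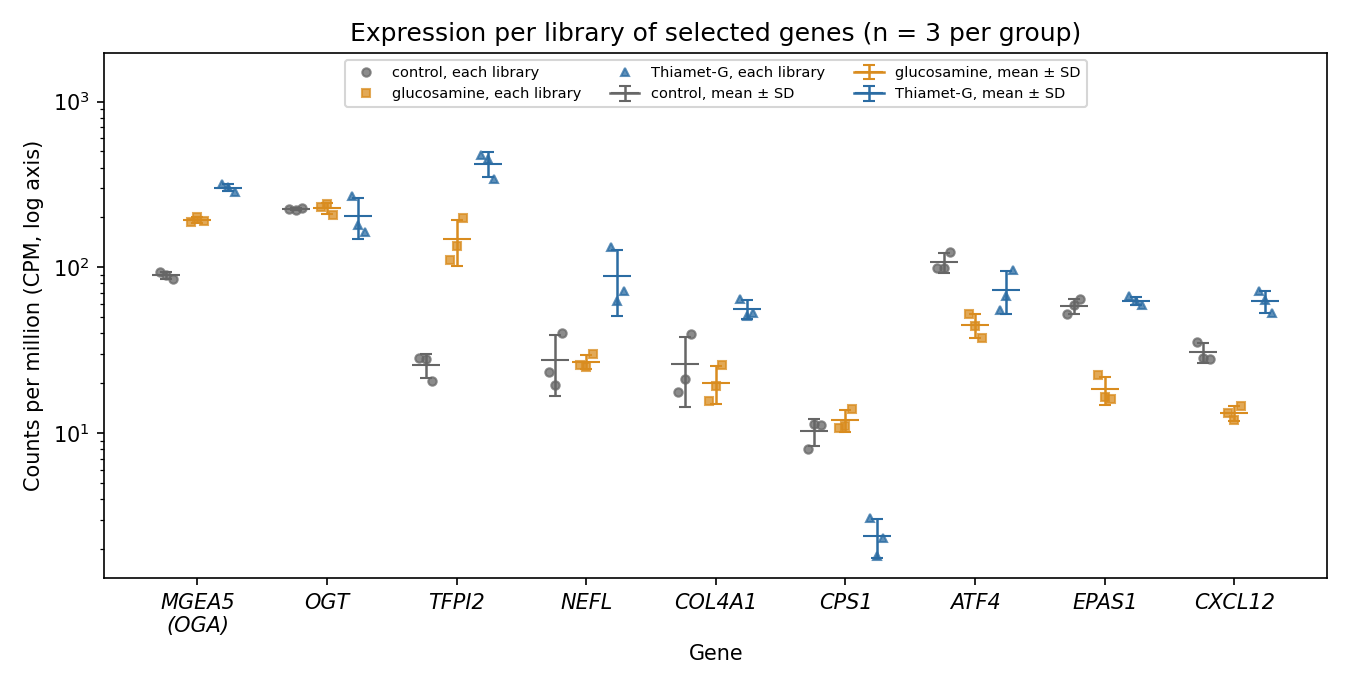
Expression of 9 genes (vertical axis, CPM, log scale) in control, glucosamine and Thiamet-G libraries; points are single libraries and bars are mean ± SD (n = 3). MGEA5 lay at 89.7 CPM in controls, 193 CPM with glucosamine and 303 CPM with Thiamet-G, while OGT lay at 225, 227 and 205 CPM.

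Of the gene groups, extracellular matrix and adhesion genes were higher with Thiamet-G. Of 29 tested members 4 rose and 25 did not pass, and adjusted over the list alone 6 rose and 1 fell (median log2 fold change 0.32, camera adjusted p = 0.000179, adjusted p = 0.222 with an estimated correlation). With the GC trend removed 7 rose and 1 fell. SPARCL1 rose by 2.91 (0.887 ± 0.407 to 6.48 ± 3.10 CPM), and ITGA9 by 1.01, a call lost without Thiamet-G 1 (adjusted p = 0.0623). The basement-membrane collagens COL4A1 and COL4A2, which lie head to head on chromosome 13 with overlapping ends (110148963 to 110307157 and 110305812 to 110513209), rose by 1.10 and 1.11. COL4A1 was not called without control 1, control 2 or any 1 of the Thiamet-G libraries (adjusted p = 0.0531 to 0.199), and COL4A2 not without any 1 of the 6 libraries (0.096 to 0.232). The ATF4 and amino acid response genes were lower as a group, with 0 rises and 1 fall among 28 (also 1 fall adjusted over the list alone). Their median was -0.33 (camera adjusted p = 0.000616, adjusted p = 0.222 with an estimated correlation). With the GC trend removed 2 members of the group fell and its median was -0.20. The member changed in the main test was the alanyl-tRNA synthetase gene AARS (log2 fold change -0.99, adjusted p = 0.0473), which was lost without control 2, control 3 or any 1 of the Thiamet-G libraries (0.0702 to 0.441), the range over all settings that ended the call being 0.056 to 0.441. The mitochondrial ribosomal proteins had 0 changed members of 45, and 0 adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.0342, adjusted p = 0.568 with an estimated correlation). This call was lost without Thiamet-G 1 (adjusted p = 0.0818), control 1 (0.164) or control 2 (0.143).

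Other groups held changed members without a call for the group in the uncorrected data. With the GC trend removed camera called further groups: NRF2 antioxidant response (adjusted p = 0.0250), mesenchymal and Schwann-like markers (0.0201), cell cycle (0.0361), p53 targets (0.0175) and immediate early genes (0.0201) higher, and the unfolded protein response (0.0250) lower. These calls used the preset correlation. With an estimated correlation, and without the GC correction, camera gave these groups an adjusted p between 0.222 and 0.568. In neuronal differentiation 3 of 30 rose and 0 fell (4 rose adjusted over the list alone; median -0.05, mean 0.20, camera adjusted p = 0.487). These were DCX, a microtubule protein of young neurons (34.7 ± 1.18 to 150.4 ± 32.0 CPM, adjusted p = 1.1e-17), and the neurofilament genes NEFL (27.8 ± 11.1 to 88.8 ± 37.9 CPM) and NEFM (35.1 ± 9.60 to 91.3 ± 5.08 CPM). In the mesenchymal and Schwann-like markers DCN rose by 1.12, LUM by 1.25 and TWIST1 by 1.07 among 22 (4 rose adjusted over the list alone, camera adjusted p = 0.0534); TWIST1 was lost without control 2 (adjusted p = 0.0503). In noradrenergic identity 2 rose and 2 fell among 25 (4 and 3 adjusted over the list alone). SLC6A2, the noradrenaline transporter, rose by 0.95 and DDC by 0.79, while DBH fell. DDC was lost without any 1 library but Thiamet-G 1 (adjusted p = 0.0528 to 0.219). In the NRF2 antioxidant response 3 of 31 rose (3 adjusted over the list alone, camera adjusted p = 0.0552), with the glutathione transferase gene MGST1 highest (8.83 ± 0.927 to 31.0 ± 1.10 CPM, adjusted p = 1.1e-09). The others were ME1 (0.77), lost without control 1, control 2, Thiamet-G 1 or Thiamet-G 2 (0.093 to 0.182), and AKR1C1 (1.12), lost without any 1 library but control 2 (0.128 to 0.206). With log2(TPM + 1) and limma SLC6A2, DDC, DBH, LUM, TWIST1, ME1 and AKR1C1 were not called (0.117 to 0.539).

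Camera called no list of energy metabolism genes after Thiamet-G with all libraries. No member changed in nuclear complex I (33 tested, median 0.02), complexes II to V (39, median 0.04), the tricarboxylic acid cycle (32, median -0.08), glycolysis (24, median -0.12), fatty acid oxidation (22, median 0.00403) or galactose use (9, median 0.02), over all genes or adjusted over the list alone. The 13 mRNAs of mitochondrial DNA had a median of -0.77 with 0 changed (0 adjusted over the list alone, camera adjusted p = 0.137), in a comparison where control 3 held 18.5% of such mRNAs. This depended on the setting: mitochondrial DNA-encoded mRNAs were called lower with the GC trend removed (adjusted p = 0.0497), without control 1 (4.5e-05), control 2 (0.0434) or Thiamet-G 1 (0.0366), and higher without control 3 (0.0372) and without control 3 and glucosamine 1 together (0.00403). Without control 3 the lists respiratory chain complex I, nuclear (0.00904), respiratory chain complexes II to V, nuclear (0.0333) and glycolysis (0.0372) were called lower, as they were without control 3 and glucosamine 1 together (0.00403 to 0.0152), where the tricarboxylic acid cycle was too (0.0362), and glycolysis also without Thiamet-G 3 (0.0115). All these calls used the preset correlation of 0.01. The estimated correlation was 0.932 for the mitochondrial DNA-encoded mRNAs, 0.367 for complex I and 0.385 for complexes II to V. With it, and with all libraries, camera gave each of these lists an adjusted p of 0.992. The other members of O-GlcNAc cycling and the hexosamine pathway did not pass: 1 of 14, MGEA5, rose (1 adjusted over the list alone), and GFPT1 and GFPT2, which open the pathway, had log2 fold changes of 0.11 and 0.63. Among 32 cell cycle genes 0 changed (0 adjusted over the list alone). Markers of other cell types were sparse: 3 of 14 epithelial, 0 of 14 blood and endothelial and 3 of 12 glial genes were expressed enough to test, and none of them changed.

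In all, 286 of 13587 genes changed with Thiamet-G: 218 rose and 68 fell, 180 and 61 of them by at least 2-fold. At an unadjusted p under 0.05 there were 1409. The median GC content was 45.2% for the genes that rose and 48.3% for those that fell. On the genes with a GC value alone, 308 were called without GC correction (235 rises and 73 falls). The quasi-likelihood test called 163 (137 rises and 26 falls), limma-voom 171, log2(TPM + 1) with limma 69, of which 89.9% rose against 76.2% in the main test, an adjusted p under 0.01 gave 187, and removal of the GC trend gave 444 (325 rises and 119 falls). The count was 153 without Thiamet-G 1 and 170 without Thiamet-G 2, and the median, mean and camera direction differed in sign for 9 of the 29 lists, none of them called.

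Glucosamine against control asked how expression differs after a long supply of a hexosamine precursor. MGEA5 rose here as well, by 1.11 on the log2 scale (SE 0.0530, adjusted p = 3.3e-05), to 193 ± 6.91 CPM, and OGT had 227 ± 17.7 CPM (log2 fold change 0.01, adjusted p = 0.992, and -0.15 after removal of the GC trend). TFPI2 rose by 2.52 (adjusted p = 7.8e-17) to 148 ± 45.9 CPM, SV2C by 2.51 to 12.95 ± 1.40 CPM, and NEBL, a protein of actin filaments, by 2.09 (8.56 ± 0.246 to 36.5 ± 7.19 CPM). EPAS1, the gene of hypoxia-inducible factor 2 alpha (chromosome 2, 46293667 to 46386697), fell from 58.7 ± 6.17 to 18.4 ± 3.55 CPM (log2 fold change -1.68, SE 0.177, adjusted p = 1.7e-09). The transcription factor gene ATF4 (chromosome 22, 39519695 to 39522683) fell from 107 ± 14.6 to 44.9 ± 7.47 CPM (log2 fold change -1.26, SE 0.176, adjusted p = 0.000202).

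Further rises were ASB9 (2.09), the Wnt antagonist DKK2 (1.98), PDE7B (1.69), PTX3 (1.67), MGST1 (1.31) and the matrix proteoglycan LUM (1.56, to 45.7 ± 10.3 CPM). ADAMTS2, which trims procollagen (chromosome 5, 179110853 to 179345461), fell from 15.9 ± 4.44 to 2.91 ± 0.733 CPM (adjusted p = 1.3e-08). Smooth-muscle actin ACTA2 fell from 7.89 ± 3.14 to 1.39 ± 0.538 CPM, IKZF1 from 8.45 ± 3.17 to 1.74 ± 0.708 CPM and the growth factor receptor gene PDGFRA from 104 ± 9.74 to 51.3 ± 7.02 CPM. GFPT1 had 96.9 ± 13.2 CPM against 72.4 ± 6.06 in controls (adjusted p = 0.257), and 1 of 14 members of O-GlcNAc cycling and the hexosamine pathway rose (1 adjusted over the list alone). The genes of this paragraph and the preceding one that were called here also passed the quasi-likelihood test. With limma-voom ASB9, DKK2, PDE7B, PTX3, ACTA2 and IKZF1 were not called (adjusted p = 0.0535 to 0.11), and with log2(TPM + 1) none but TFPI2 and EPAS1 was (0.17 to 0.377 for MGEA5, SV2C, NEBL, ATF4 and the others).

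The 4 groups that camera called were all lower with glucosamine, in libraries whose expression of GC-rich genes was lower than in controls. Of 57 cytosolic ribosomal protein genes 8 fell and 0 rose (15 fell adjusted over the list alone; median -0.43, camera adjusted p = 1.7e-08, adjusted p = 0.610 with an estimated correlation). Among them were RPS10 (log2 fold change -1.96) and RPL28 (-1.03). Of 30 neuronal differentiation genes 5 fell and 0 rose (7 fell adjusted over the list alone; median -0.45, camera adjusted p = 0.0013, adjusted p = 0.546 with an estimated correlation), among them the adhesion gene L1CAM (-1.15), the vesicle protein gene VAMP2 (-1.18) and the growth-cone gene GAP43 (-0.70). Of 24 glycolysis genes 2 fell and 0 rose (5 fell adjusted over the list alone; median -0.55, camera adjusted p = 0.00533, adjusted p = 0.610 with an estimated correlation). These were PKM (955.5 ± 400.1 to 355 ± 136 CPM) and GAPDH (1180 ± 171 to 519 ± 178 CPM), which has 65 pseudogenes. Of 28 ATF4 and amino acid response genes 5 fell and 0 rose (5 fell adjusted over the list alone; median -0.35, camera adjusted p = 0.00533, adjusted p = 0.546 with an estimated correlation), with ATF4 first. After removal of the GC trend the members that fell numbered 5 of 57 for cytosolic ribosomal proteins, 2 of 30 for neuronal differentiation, 1 of 24 for glycolysis and 1 of 26 for the ATF4 and amino acid response, whose median moved to -0.19. The glycolysis call was lost (median -0.29, adjusted p = 0.0597) and GAPDH (0.069) and L1CAM (0.242) were not called. With the preset correlation camera still called cytosolic ribosomal proteins (adjusted p = 1.2e-05), neuronal differentiation (5.4e-05) and the ATF4 and amino acid response (0.0187) lower. Of all 353 genes called lower with glucosamine, 343 had a GC value and could be tested again, and 147 stayed lower. Immediate early genes were then called higher as a group (median 0.58, camera adjusted p = 0.00451 with the preset correlation). Before the correction they had adjusted p = 0.610 with an estimated correlation.

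Outside these groups, 4 of 39 genes of complexes II to V fell (5 adjusted over the list alone, camera adjusted p = 0.172), COX4I1 by 1.23 on the log2 scale. In complex I 0 of 33 changed (3 fell adjusted over the list alone; median 0.12, mean -0.08, camera direction down). The mitochondrial DNA mRNAs had a median of -0.78 with 0 of 13 changed (0 adjusted over the list alone, camera adjusted p = 0.114), again against control 3 with its 18.5%. The list of mitochondrial DNA-encoded mRNAs was called lower with the GC trend removed (median -0.81, adjusted p = 0.0187) and without control 1 (7.3e-05), control 2 (0.022) or glucosamine 1 (0.00483). Without control 3 respiratory chain complex I, nuclear (0.0209) and respiratory chain complexes II to V, nuclear (0.000567) were called lower, and without control 3 and glucosamine 1 together as well (0.00227 and 0.000144). These list calls used the preset correlation. The estimated correlation was 0.932 for the mitochondrial DNA-encoded mRNAs, 0.367 for complex I and 0.388 for complexes II to V. With it, and with all libraries, camera gave adjusted p = 0.789, 0.915 and 0.789. In noradrenergic identity 2 rose and 5 fell of 25 (2 and 6 adjusted over the list alone), with HAND1 at -1.20 and CHGB at -1.14. With the GC trend removed 3 rose and 2 fell in that list (median 0.30), and 2 fell in complexes II to V. In the unfolded protein response 3 of 25 fell (3 adjusted over the list alone), with HYOU1 at -1.25 and CALR at -1.28. Extracellular matrix genes had 1 fall among 29, the laminin gene LAMA1 at -0.91 (2 fell adjusted over the list alone, camera adjusted p = 0.114), and FADS2, a fatty acid desaturase whose exons touch those of its neighbours FADS1 and FEN1, changed by -1.85. Of the glial markers PDGFRA fell, as did SLC1A2, at 1.17 ± 1.08 CPM in controls and 0.101 ± 0.133 CPM with glucosamine.

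Many of these members rested on few libraries. RPS10, RPL28, L1CAM, VAMP2, GAP43, PKM, GAPDH, COX4I1, HAND1, CHGB, HYOU1, CALR, LAMA1, SLC1A2 and FADS2 did not pass the quasi-likelihood test (adjusted p = 0.0542 to 0.131). Without glucosamine 2 all of them except FADS2 were lost (0.0677 to 0.241). Without glucosamine 3, RPL28, L1CAM, VAMP2, GAP43, PKM, GAPDH, COX4I1 and LAMA1 were lost (0.0715 to 0.135). Without control 3, L1CAM, VAMP2, GAP43, PKM, GAPDH, COX4I1 and LAMA1 were lost (0.0514 to 0.0976), without control 2 L1CAM, GAP43, GAPDH, LAMA1 and SLC1A2 (0.0549 to 0.287), without control 1 GAP43 (0.0507) and without glucosamine 1 SLC1A2 (0.0797). Over all settings that ended a call the adjusted p of these genes reached 0.71 (SLC1A2, log2(TPM + 1) with limma).

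In all, 456 of 13587 genes changed with glucosamine: 103 rose and 353 fell, 74 and 304 by at least 2-fold, with 2670 at an unadjusted p under 0.05. The genes that fell had a median GC content of 56.6%, those that rose 42.1% and all tested genes 46.4%. On the genes with a GC value alone, 547 were called without GC correction (121 rises and 426 falls). The quasi-likelihood test called 38 genes (21 rises and 17 falls), limma-voom 20, log2(TPM + 1) with limma 3 (66.7% rises against 22.6% in the main test, with the median of all genes at 0.16), no filter 287 and an adjusted p under 0.01 161, while removal of the GC trend gave 337 genes (155 rises and 182 falls, 46.0% rises), and 69 with the quasi-likelihood test as well. The count was 1001 without glucosamine 1, 67 without glucosamine 2 (36 rises and 31 falls), 171 without glucosamine 3 and 270 without control 2, and 1399 without control 3 and glucosamine 1 together; median, mean and camera direction differed in sign for 7 of the 29 lists, none of them called.

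Thiamet-G against glucosamine asked how the treatments differ from each other. GREM1 was higher by 3.77 on the log2 scale (SE 0.761, adjusted p = 5.9e-12), with 38.7 ± 10.7 CPM against 2.82 ± 1.85 CPM, and the chemokine gene CXCL12 (chromosome 10, 44370165 to 44386493) by 2.25 (SE 0.152, adjusted p = 7.4e-16), with 62.8 ± 9.40 against 13.3 ± 1.35 CPM. EPAS1 was higher by 1.78 (SE 0.160, adjusted p = 3.2e-11), at 62.9 ± 3.62 CPM against 58.7 ± 6.17 CPM in controls. CPS1 was lower (log2 fold change -2.31, SE 0.243, adjusted p = 1.1e-07), as were AASS (-2.10) and FGL1 (-2.11). MGEA5 was higher by 0.65 (SE 0.0529, adjusted p = 0.0423), but lost its call with the quasi-likelihood test (adjusted p = 0.0739), without any 1 of the 6 libraries (0.0868 to 0.228) and with library size scaling (0.118).

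Other genes higher with Thiamet-G were TSHZ2 (2.42), RERG (2.35), the vesicle-trafficking gene RPH3A (2.29) and SEZ6L (2.33, from 5.78 ± 0.862 to 29.1 ± 0.970 CPM). CKMT1A, a mitochondrial creatine kinase with a near-identical copy, CKMT1B, was higher by 2.15. Lower were CHAC2 (-2.25), PLOD2 (-2.13), the neuroendocrine transcription factor gene INSM1 (-2.03, from 18.2 ± 5.99 to 4.45 ± 0.630 CPM), CBLN1 (-1.62) and the axon guidance gene SEMA3A (-1.58). PDGFRA was higher by 1.22. With log2(TPM + 1) and limma TSHZ2, RERG, CKMT1A, CHAC2, PLOD2, INSM1, CBLN1, SEMA3A and PDGFRA were not called (adjusted p = 0.0586 to 0.266), and with limma-voom neither CHAC2 (0.0697) nor CKMT1A (0.0519).

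Of 30 neuronal differentiation genes 4 rose and 1 fell (13 and 2 adjusted over the list alone; median 0.53, camera adjusted p = 6.2e-07, adjusted p = 0.154 with an estimated correlation). NEFM rose by 2.11, DCX by 1.87, NEFL by 1.72 and the heavy neurofilament gene NEFH by 1.94. Of 29 extracellular matrix and adhesion genes 5 rose and 0 fell (13 and 1 adjusted over the list alone; median 0.54, camera adjusted p = 1.4e-09, adjusted p = 0.144 with an estimated correlation), with ITGA9 at 1.58, COL4A1 at 1.47, COL4A2 at 1.46 and SPARC at 0.82. Of 22 mesenchymal and Schwann-like markers 4 rose and 0 fell (8 adjusted over the list alone; median 0.50, camera adjusted p = 0.000197, adjusted p = 0.235 with an estimated correlation), with ANXA2 at 1.21 and the hyaluronan receptor gene CD44 at 1.57. Of 57 cytosolic ribosomal proteins 3 rose and 0 fell (9 adjusted over the list alone; median 0.50, camera adjusted p = 2.9e-11, adjusted p = 0.460 with an estimated correlation), with RPS10 at 1.91 and RPL10 at 1.37. Mitochondrial biogenesis and dynamics was lower, with 1 fall among 29, the mitochondrial protease gene OMA1 at -1.14 (1 adjusted over the list alone; median -0.30, camera adjusted p = 0.0135, adjusted p = 0.446 with an estimated correlation). With the GC trend removed 7 neuronal differentiation genes, 8 extracellular matrix genes, 5 mesenchymal and Schwann-like markers and 1 cytosolic ribosomal protein gene rose. The call of mitochondrial biogenesis and dynamics was lost after removal of the GC trend (adjusted p = 0.103) and without Thiamet-G 1 (0.0546).

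Among these members NEFH, SPARC, RPS10 and RPL10 did not pass the quasi-likelihood test (adjusted p = 0.0545 to 0.155), and RPL10 was lost after removal of the GC trend (0.0557). Without glucosamine 2, NEFH, SPARC, RPS10, RPL10, COL4A2, CD44 and OMA1 were lost (0.059 to 0.254), and without Thiamet-G 3 all of these except CD44 (0.0655 to 0.593). Without Thiamet-G 2, SPARC, CD44 and RPL10 were lost (0.0541 to 0.0629), without glucosamine 1 RPS10 and RPL10 (0.0678 and 0.082), and without glucosamine 3 NEFH and RPL10 (0.0998 and 0.0629).

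In all, 334 genes differed between the treatments: 239 were higher with Thiamet-G and 95 lower, 203 and 75 by at least 2-fold, with 1869 at an unadjusted p under 0.05. The median GC content was 49.1% for the genes that were higher and 39.9% for those that were lower. On the genes with a GC value alone, 373 were called without GC correction (267 higher and 106 lower). Removal of the GC trend gave 444 genes (297 higher and 147 lower). The quasi-likelihood test called 133 (102 higher and 31 lower), limma-voom 117, log2(TPM + 1) with limma 19 (89.5% higher against 71.6% in the main test) and an adjusted p under 0.01 155. The count was 125 without glucosamine 2, 205 without glucosamine 3, 160 without Thiamet-G 2, 147 without Thiamet-G 3 and 963 without control 3 and glucosamine 1 together, and median, mean and camera direction differed in sign for 3 of the 29 lists, none of them called.

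A comparison of both sets of calls asked which genes moved alike under the treatments. Shared genes were ranked by the smaller of their changes under the treatments. Among genes with a mean of at least 5 CPM, TFPI2, SV2C, NEBL, ASB9 and DKK2 had the largest shared rises by this ranking. NEBL rose by 2.16 with Thiamet-G and by 2.09 with glucosamine, ASB9 by 1.95 and 2.09, and DKK2 by 1.90 and 1.98. MGEA5 was also among the shared rises. IGF2, the gene of insulin-like growth factor 2 (chromosome 11, 2129112 to 2158391), had 171.5 ± 62.9 CPM in controls, 67.8 ± 12.4 CPM with glucosamine and 61.4 ± 3.87 CPM with Thiamet-G. It shares exons with INS-IGF2 and IGF2-AS. With the GC trend removed its call with glucosamine was lost (adjusted p = 0.0756). DBH, HMGA1, PIPOX (log2 fold changes -1.52 with Thiamet-G and -1.73 with glucosamine) and TNNT2 (-1.25 and -1.77) were the other largest shared falls above that CPM limit by the same ranking. Without control 3 HMGA1 was called in neither treatment (adjusted p = 0.715 with Thiamet-G and 0.133 with glucosamine), and without glucosamine 2 it was not called with glucosamine (0.108). CXCL12, FBN1 and TNR changed in opposite directions; they were all that did so.

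In all, 53 genes rose and 11 fell under both treatments, where 1.65 and 1.77 would be shared by independent sets of those sizes. Simulated treatments without effect against the shared controls gave at most 2 shared rises and 1 shared fall in 20 runs. Each library and each gene was drawn independently there. Neither a deviation common to the controls nor one shared by many genes was therefore covered. Across genes, which are not independent replicates, the log2 fold changes of the treatments had a correlation of 0.517, against 0.502 on average and 0.520 at most in the simulations, and a covariance of 0.231, against 0.105. Since both treatments were set against the same 3 controls, which are too few to split, part of the excess may come from the shared controls. The quasi-likelihood test kept 20 of the shared rises and 1 of the shared falls. With the GC trend removed the exact test kept 45 of the rises and 5 of the falls. The quasi-likelihood test then kept 27 and 0. Shared genes without a GC value were not tested after the correction and count as not kept. Shared falls numbered 33 without control 1, 17 without control 2, 4 without control 3, 20 without glucosamine 1, 2 without glucosamine 2, 7 without glucosamine 3, 2 without Thiamet-G 1, 3 without Thiamet-G 2 and 39 without Thiamet-G 3, while shared rises ranged from 27 to 69. The shared genes numbered 29 without glucosamine 2, 37 without glucosamine 3, 37 without Thiamet-G 2 and 108 without control 3 and glucosamine 1 together.

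**Figure D3:**
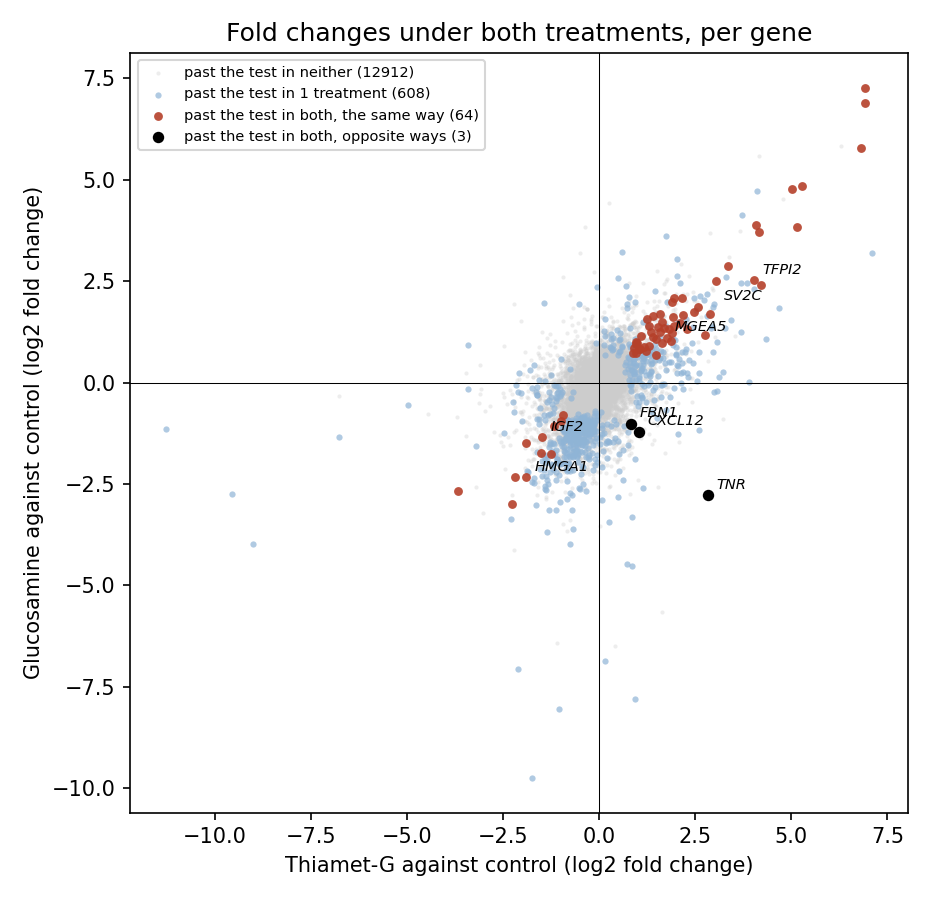
Log2 fold change per gene with Thiamet-G (horizontal axis) and with glucosamine (vertical axis), both against control; each point is a gene, coloured by the number of treatments in which it passed the exact test, and genes without counts in a group lie far out, at values that depend on the prior count. Of the genes drawn, 64 changed the same way in both treatments, 3 changed in opposite ways and 608 changed in 1 treatment.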

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

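Among the tests below, those of the glucosamine treatment itself and of the shared control libraries were chosen only after the result was seen, and the GC corrections were added after the data were seen.

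CXCL12, FBN1 and TNR moved in opposite directions under the treatments; they were chosen for opposite calls against the same controls, so a difference between the treatments follows in large part from that choice. The log2 fold change with Thiamet-G minus that with glucosamine was 2.25 for the chemokine gene CXCL12, 1.83 for the fibrillin gene FBN1 (chromosome 15, 48408313 to 48645721) and 5.61 for the brain matrix gene TNR (chromosome 1, 175315194 to 175743595). A GC trend between libraries was argued against as the source of these differences, which were 2.14, 1.75 and 5.55 once it was removed. That 3 of the 3 genes kept their call between the treatments adds little, since genes chosen in this way were likely to keep it. As to a single deciding library, 3 kept that call whichever library was left out, which the choice also made likely. A single deciding library stays open for the calls of FBN1 against control, which were lost with Thiamet-G without Thiamet-G 1, 2 or 3 (adjusted p = 0.441, 0.0534 and 0.0698), with glucosamine without glucosamine 2 (0.0916), and in the quasi-likelihood test (0.127 and 0.0781). TNR rests on few counts with glucosamine (0.1497 ± 0.135 CPM, n = 3) and had adjusted p = 0.0805 there in the quasi-likelihood test.

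More genes fell than rose with glucosamine in the exact test, 353 against 103, but not in the quasi-likelihood test (17 against 21). Part of this may come from the GC trend between libraries, because on the same genes 426 were called lower before the trend was removed and 182 after, 42.7% of that number. The choice of libraries leaves the matter open: 220 genes were called lower without control 3, 62.3% of the main number, 120 without glucosamine 3, and 31 without glucosamine 2, where 36 rose and the excess was gone. The treatment itself could also have produced the trend, and this could not be separated, since the lowest correlation of expression with GC content in controls lay 0.154 above the highest with glucosamine. Of the 10 splits of the 6 libraries 1, the real one, gave 456 genes and the highest other 113. With the GC trend removed they gave 337 and 180, on the genes with a GC value only. However, 10 splits are too few for a share under 0.05.

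Many genes rose under both treatments, 53 in number. Spread of the shared control libraries that is independent between libraries and between genes was argued against as the only cause, since simulated treatments without effect gave at most 2. A deviation common to the control libraries stays open, because the simulations drew each library independently. They also drew each gene independently and held no GC trend, so library spread shared by many genes was not covered. The correlation of the log2 fold changes across all genes, 0.517, lay within the simulated range (0.520 at most). The GC trend was argued against too as the source of most of them, since 45 of the 53 kept both calls once it was removed. The quasi-likelihood test kept 20 of them before the removal and 27 after. On the same genes 59 shared rises were called before its removal and 75 after (127% of that number). The 75 include genes not shared before, so that total does not bear on the first calls. A part of the calls may rest on 1 library, as 27 shared rises were called without glucosamine 2, 50.9% of the number with all libraries.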

How the results depend on the processing

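The tests of the glucosamine treatment itself and of the shared control libraries were chosen only after the result was seen; the GC corrections and the omission of control 3 with glucosamine 1 were added after the data were seen. The cause of the differences between settings was not tested. Counts with the GC trend removed cover only the genes with a GC value. Genes changed with Thiamet-G numbered 286, and 163 with the quasi-likelihood test, 171 with limma-voom, 69 with log2(TPM + 1), 108 with a replicate block, 444 with the GC trend removed, 187 at an adjusted p under 0.01, and 153 to 278 with 1 library left out. With glucosamine they numbered 456, and in the same order 38, 20, 3 and 15, then 287 without a filter, 69 with the GC trend removed and the quasi-likelihood test, 161 at an adjusted p under 0.01, 1399 without control 3 and glucosamine 1, and 67 to 1001 with 1 library left out. Between the treatments they numbered 334, and 133, 117, 19 and 67 in that order, then 155 at an adjusted p under 0.01, 963 without both libraries, and 125 to 389 with 1 left out. Genes called in both treatments numbered 64, and 21 with the quasi-likelihood test, 8 with the block, 108 without both libraries, and 29 to 89 with 1 left out. Lists called with Thiamet-G numbered 3, and 0 with an estimated correlation, 8 with mixed fry, 7 with the block, 10 with the GC trend removed, 12 without both libraries, and 3 to 9 with 1 left out. Of the 3, mixed fry called only extracellular matrix and adhesion (adjusted p = 1.4e-06). With glucosamine 4 lists were called, and 0 with an estimated correlation, 1 and 7 with directional and mixed fry, 8 without both libraries, and 4 to 7 with 1 left out. Directional fry called none of the 4: its 1 list was O-GlcNAc cycling and the hexosamine pathway, higher (adjusted p = 0.0352). Mixed fry, which has no direction, called only neuronal differentiation of the 4 (adjusted p = 0.00536). Between the treatments 5 were called, and 0 with an estimated correlation, 9 without both libraries, and 5 to 8 with 1 left out. The block is doubtful, as same-numbered libraries had correlations of -0.316 to 0.207 and 1 of 9 libraries correlated best with its own number. With Thiamet-G the list of mitochondrial DNA-encoded mRNAs was called lower in some settings and higher in others. Among named genes, signs turned only for those that were never called. OGT with glucosamine went from 0.01 to -0.0769 with upper quartile factors, -0.00175 with only 6 libraries, -0.153 with the GC trend removed by either test, -0.0199 without both libraries, and -0.00521, -0.00211 and -0.0322 without control 3, glucosamine 1 and glucosamine 2 (-0.0322 to 0.0542 with 1 left out). With Thiamet-G OGT went to 6.7e-05 without Thiamet-G 3 (-0.383 to 6.7e-05 with 1 left out), and GFPT1 to -0.0285 without Thiamet-G 1 (-0.0285 to 0.223).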

Other observations

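The genes in this part, like the tests of the glucosamine treatment itself and of the shared control libraries, were chosen only after the result was seen.

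H19, the noncoding gene beside IGF2 (chromosome 11, 1995166 to 2004552), fell with Thiamet-G (log2 fold change -3.67, adjusted p = 6.9e-06) and with glucosamine (-2.67, adjusted p = 0.00298, 0.0773 in the quasi-likelihood test and as high as 0.09998 with 1 library left out), from 4.94 ± 2.92 CPM in controls to 0.382 ± 0.224 and 0.771 ± 0.178 CPM (n = 3). IGF2 fell as well (-1.48 and -1.34), the latter with adjusted p = 0.0756 once the GC trend was removed. PEG10, an imprinted gene of chromosome 7, rose by 1.46 with Thiamet-G (adjusted p = 3.4e-06) and had a log2 fold change of 0.55 with glucosamine (adjusted p = 0.197). Its neighbour SGCE rose by 0.84 with Thiamet-G (adjusted p = 0.0332, 0.0930 in the quasi-likelihood test and as high as 0.326 with 1 library left out). The Wnt antagonist gene DKK1 rose with Thiamet-G and glucosamine by 1.70 and 1.35 (133.5 ± 30.03 CPM in controls, 433 ± 22.8 with Thiamet-G), and the transcription factor gene ZIC5 by 4.16 and 3.70 from 0.174 ± 0.113 CPM.

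With Thiamet-G the GABA transporter gene SLC6A11 rose by 4.67 (0.151 ± 0.181 to 4.41 ± 0.930 CPM), and the opioid receptor gene OPRM1 rose by 2.28 (1.73 ± 0.429 to 8.32 ± 0.666 CPM). With glucosamine the secreted CCL2 and MGP fell (-2.61 and -1.23), and between the treatments they differed by 3.74 (adjusted p = 1.1e-08) and 1.99 (adjusted p = 3.3e-11). HHIP, which binds hedgehog ligands, fell with Thiamet-G (-3.42).

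A rise of the O-GlcNAcase gene under both treatments, without a call for OGT, may be a response to raised O-GlcNAc. O-GlcNAc was not measured here, so such a response was not tested. Blots of O-GlcNAc and of both enzymes over the weeks of treatment, and after wash-out, would test it. The joint fall of IGF2 and H19 could follow loss of a shared enhancer, which was not tested. With Thiamet-G the fall did not rest on 1 library (adjusted p at most 0.00205 for H19 and 0.00122 for IGF2 with any 1 left out). IGF2 had adjusted p = 0.0548 there with the GC trend removed and the quasi-likelihood test. Enhancer activity in the region, measured in more cultures, would test such a loss. A gain or loss of a whole chromosome in most cells is a less likely source of the differences. With the GC trend removed, the largest median shift of a chromosome was -0.0707 on the log2 scale with Thiamet-G and -0.0898 with glucosamine, both on chromosome 19. Small shifts did pass the permutation test: chromosome 19 (adjusted p = 0.0023 in both), chromosome 8 (0.00345 with Thiamet-G and 0.00537 with glucosamine), chromosome 7 with Thiamet-G (0.0383) and chromosome 11 with glucosamine (0.0023). That test shuffled genes over chromosomes as if they were independent, so its p-values do not cover the spread between libraries. A change in a minority of cells was not tested and stays open.

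The splits of the libraries bound the counts only loosely. For Thiamet-G against control 1 of the 10 splits, the real one, gave 286 genes and the highest other 6. For Thiamet-G against glucosamine 1 of the 10 gave 334, and the highest other, which puts glucosamine 1 with Thiamet-G 2 and Thiamet-G 3, gave 316. That split may follow the GC trend, since with the trend removed, on the genes with a GC value, it gave 46 genes and the real one 444. For glucosamine against control the highest other split gave 113 genes and the real one 456, against 180 and 337 with the trend removed. The values with the trend removed cover only the genes with a GC value, on which the real split gave 547 without correction. Other splits were not run on those genes without correction, so the change from 113 to 180 cannot be credited to the removal. In each comparison, 10 splits are too few for a share under 0.05.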
